A study of Planococcus kocurii with 2 samples.

How the data were processed

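RNA was taken from cultures of Planococcus kocurii O516 after 24 h at 1 library per condition, with and without sulfamethoxazole in the broth. Per the labels' protocols, total RNA was freed of ribosomal RNA and made into strand-marking libraries with selection of short cDNA fragments, and sequencing was on an Illumina HiSeq instrument. CASAVA 1.8.2, Bowtie2 2.2.3 and HTSeq 0.6.1 were named in the submitters' processing notes. The authors counted reads per gene with HTSeq and deposited FPKM values (fragments per kilobase of gene, scaled to the size of the library), computed from each gene's count and length, per the labels. The genome build, the annotation and the strand setting of the counting were not given in the sources used here. The authors' text also describes a scaling factor and fold changes. Those belong to a later step, and their fold changes were not used here.

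The files hold 1 FPKM value for each of 3438 locus identifiers, with no gene names. The plan assumed that names or products might be at hand. Without them, the 26 gene lists fixed in advance were not tested, and the rule for printing genes fell back to its own provision for this case: the 2 identifiers with the highest and the 2 with the lowest centred difference. The rule's other parts, the most abundant genes and the runs of neighbours, are given by rank and by number. Gene copies were not compared, so reads shared between near-identical genes could not be marked.

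FPKM are not counts, so no count model was applied, and with 1 library per condition no test of the condition was made. The main value of a gene was the difference of log2(FPKM + 1) with minus without the drug, minus the median of that difference over the 1145 genes at 10 FPKM or more in both libraries (0.38). This centring was chosen because the deposited text scales libraries before comparing them. Genes at 10 FPKM or more in 1 or both libraries were counted, 1297 in all, at 2-fold and at 4-fold. Alternatives were no centring, a trimmed mean of the ratios (30% of ratios and 5% of mean values trimmed at each end), TPM, pseudocounts of 0.1 and 10, no filter, and a filter at 50 FPKM. These choices were made before the data were examined. Chosen after seeing the data were the recovery of reads described next, the counts of genes by counting interval, a minimum of 20 reads, scaling without the most abundant pair of genes, and the use of identifier order.

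Read numbers were recovered from the deposited FPKM because each value is a whole number of reads divided by a whole gene length and by the library total. The most common FPKM ratio of the libraries, shared by 97 genes, was 1.13, which is the ratio of their read totals. Gene lengths from 60 to 12000 bp in multiples of 3 were searched for the shortest at which both of a gene's values were whole reads, with a relative tolerance of 5e-09. A gene with no such fit was given the shortest whole length of any kind. All 2148 genes with a value above 0 in either library came out whole when every length in that range was allowed. The library totals came out as 3180458 with the drug and 3607368 without it. The most abundant pair of genes could not have lengths in multiples of 3 without exceeding a library's total, so the shortest whole length was used for these. The recovered reads summed to 98.4% and 98.7% of the totals. Where a gene's reads in both libraries and its length share a factor, the recovered reads are too few by that factor. The ratio is then unaffected and its counting interval too wide. Genes with a length that is not a multiple of 3 could be assigned too many reads.

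Intervals of read ratios are 95% exact Clopper-Pearson intervals of the share of a gene's reads that came from the library with the drug, converted to a ratio and centred in the same way. Intervals and floors (3 reads for a count of 0) cover counting error only. A gene above 0 had a median of 45 reads with the drug and 46 without it. On simulated libraries with the recovered levels and gene lengths, 87.6% of 2100 genes had their reads recovered exactly and the totals were recovered. Because the recovered lengths were taken as true, this could not show errors for genes whose real length is not a multiple of 3. Of 100 genes seeded at 4-fold in each direction, 99 of the higher and 100 of the lower passed the 10 FPKM filter, and all of these were at least 2-fold apart in the right direction. Of 1072 unchanged genes, 8 were at least 2-fold apart. Of values shifted off the grid, 0.667% still came out as whole reads.

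Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.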

Results

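Transcript levels were measured by RNA sequencing in Planococcus kocurii O516, a Gram-positive bacterium, grown for 24 h in Mueller-Hinton broth with or without sulfamethoxazole. Sulfamethoxazole is a sulfonamide that inhibits dihydropteroate synthase, an enzyme of bacterial folate synthesis. There was 1 library per condition and no replicate, so every difference below is a difference between these 2 libraries, with no test of the condition and no p-value. The same 3438 genes were listed in both libraries. The read totals behind the FPKM values, worked out from the values themselves, were 3180458 with the drug and 3607368 without it. The data identify genes by locus identifiers only and do not pair these with gene names. The folate, nucleotide, stress and transport gene lists chosen in advance were therefore not filled, and no gene position or annotation is given. At most 2 identifiers are printed for each direction.

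The reads of both libraries were dominated by 1 short gene, which took a smaller share of the reads in the library with sulfamethoxazole. This most abundant gene held 43.0% of the reads with the drug (95% exact Clopper-Pearson interval 42.96% to 43.06%) and 56.1% without it (56.07% to 56.17%). Its deposited FPKM were 1211535 and 1580932, 1.30-fold lower with the drug. The second most abundant gene held 4.81% of the reads with the drug and 6.41% without it, and its FPKM were 1.33-fold lower with the drug. Relative to the median gene, the centred log2 differences of these genes were -0.77 and -0.80, and both stayed below 0 under each scaling tried that kept their reads. The gene lengths that fitted their values were 355 and 379 bp, neither a multiple of 3. The intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. These are shares of libraries made after removal of ribosomal RNA and selection of short fragments. They need not be shares of the RNA in the cells, and an effect of these steps on them was not tested.

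The genes that ranked 3 to 10 with sulfamethoxazole had higher deposited FPKM in that library, by 1.12- to 2.12-fold. After centring on the median gene, 5 of these 8 genes remained above 0, over a range from -0.22 to 0.70 on the log2 scale. Of the 10 most abundant genes of each library, 8 were shared, and of the 100 most abundant, 89 were shared. The 10 genes with the most reads held 62.3% of the read total behind the FPKM values with the drug and 72.3% without it. The 100 genes with the most reads held 83.0% and 87.5%. That total need not hold every sequenced read.

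**Figure D1:**
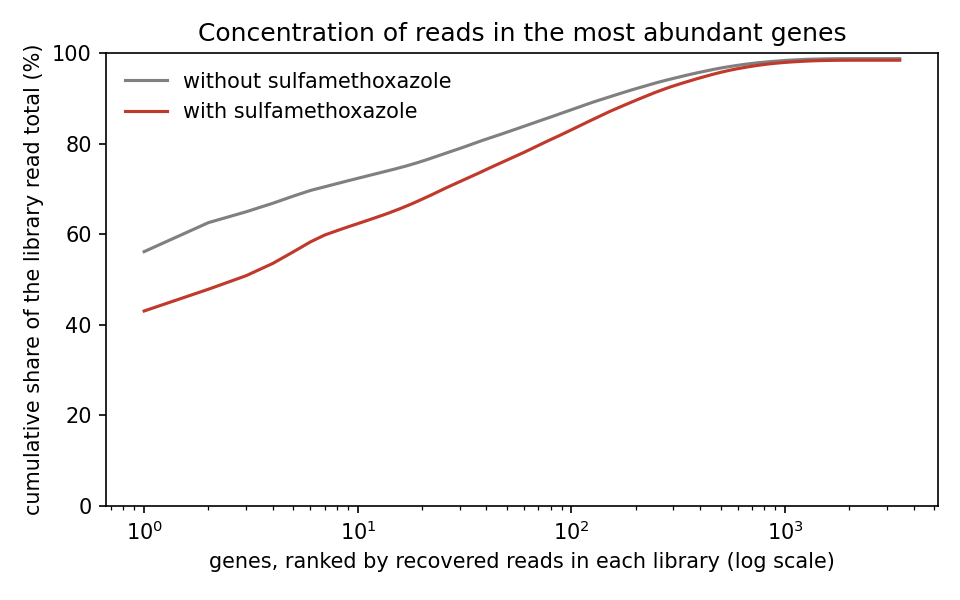
Cumulative share of the library's read total (vertical axis, percent) held by genes ranked from the most to the fewest reads (horizontal axis, log scale), 1 line per library. The line without sulfamethoxazole starts at 56.1% and the line with it at 43.0%, and at 100 genes they stand at 87.5% and 83.0%.

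A large part of the listed genes had no counted reads in either condition. Of the 3438 genes, 1359 (39.5%) were at 0 with sulfamethoxazole and 1406 (40.9%) without it, and 1290 (37.5%) were at 0 in both. By counting error alone, a count of 0 allows up to 0.943 FPKM with the drug and 0.832 FPKM without it for a gene of 1 kb. This limit does not cover reads of a gene that were left uncounted, which could not be assessed here. These genes were therefore not detected here, which does not show them to be silent. Reads were found only with the drug for 116 genes and only without it for 69. These genes were all under 10 FPKM, with at most 17 reads and 7.42 FPKM in the former group and at most 6 reads and 4.02 FPKM in the latter. At 10 or more reads there were 4 genes seen only with the drug and 0 seen only without it.

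The question of the series was how expression differs with sulfamethoxazole in the medium. Among the 1297 genes with at least 10 FPKM in 1 or both libraries, most differed little: 952 (73.4%) lay within 1.5-fold of the median ratio and 1176 (90.7%) within 2-fold. The higher group at 2-fold held 63 genes, with a median of 57.9 FPKM with the drug against 11.1 without it. The lower group held 58 genes, with a median of 18.7 FPKM with the drug against 39.5 without it. At 4-fold, 16 genes were higher and 4 were lower. Over the alternative scalings, pseudocounts and filters, the 4-fold counts ran from 9 to 26 higher and from 1 to 12 lower. The split depended on scaling: the FPKM as deposited, whose median gene was 1.31-fold higher with the drug (0.38 on the log2 scale), gave 151 genes at least 2-fold higher and 17 lower. Values set to equal totals as TPM gave 154 and 12, and values without the reads of the most abundant pair of genes gave 59 and 80. Neither of these was centred on the median gene, unlike the main counts. Folds are on the log2(FPKM + 1) scale, which understates the difference for low genes.

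By the centred log2 difference, the most different genes on the higher side were DBR31_RS13930 and DBR31_RS03325. DBR31_RS13930 stood at 57.9 FPKM with the drug and 2.83 FPKM without it, a centred log2 difference of 3.56. It rested on 90 and 5 reads, a read ratio of 15.6-fold relative to the median gene with a 95% exact counting interval from 6.46 to 49.3. DBR31_RS03325 stood at 56.5 FPKM with the drug and 3.03 FPKM without it, from 181 and 11 reads. Its centred log2 difference was 3.45 and its read ratio 14.3-fold, with a counting interval from 7.80 to 29.1.

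On the lower side, the extremes by the centred log2 difference were DBR31_RS02210 and DBR31_RS15685. DBR31_RS02210 had 0.532 FPKM with the drug and 13.8 FPKM without it, from 2 and 59 reads. Its centred log2 difference was -3.66, and the read ratio was 34.0-fold lower with a wide counting interval from 8.99 to 287. DBR31_RS15685 had 4.25 FPKM with the drug and 35.4 FPKM without it, from 14 and 132 reads. Its centred log2 difference was -3.18 and its read ratio 10.9-fold lower, with a counting interval from 6.24 to 20.4. With a pseudocount of 10 in place of 1, the difference of DBR31_RS13930 was 2.07, that of DBR31_RS03325 was 2.02, that of DBR31_RS02210 was -1.51 and that of DBR31_RS15685 was -2.002. With TPM and no centring, DBR31_RS02210 stood at -2.43 and DBR31_RS15685 at -2.45. Reads shared with near-identical gene copies were not assessed for these genes.

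The genes at least 2-fold apart were concentrated at low abundance, but not confined to it. In the lowest of 5 equal classes of mean expression, 28 of 260 genes were at least 2-fold higher and 23 lower, while in the highest class 8 of 260 were higher and 5 lower. The SD of the centred log2 differences across genes was 0.92 in the lowest class and 0.49 in the highest. The filter takes a gene that reaches 10 FPKM in either library, so near that floor it favours genes that differ. The counts and the SD of the lowest class are partly set by this. Of the 538 genes with 500 or more reads over both libraries, 15 were at least 2-fold higher and 13 lower, and 5 were at least 4-fold higher and 1 lower. Counting intervals were also taken for the genes at least 2-fold apart. These genes were picked by their fold in the same reads, so the intervals are no separate support for a difference. The 95% counting interval of the read ratio lay wholly above 1 for 58 of the 63 higher genes and wholly below 1 for 56 of the 58 lower genes. It lay wholly past 2-fold for 34 higher and 15 lower genes. These intervals compare the 2 libraries and hold no spread between cultures.

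**Figure D2:**
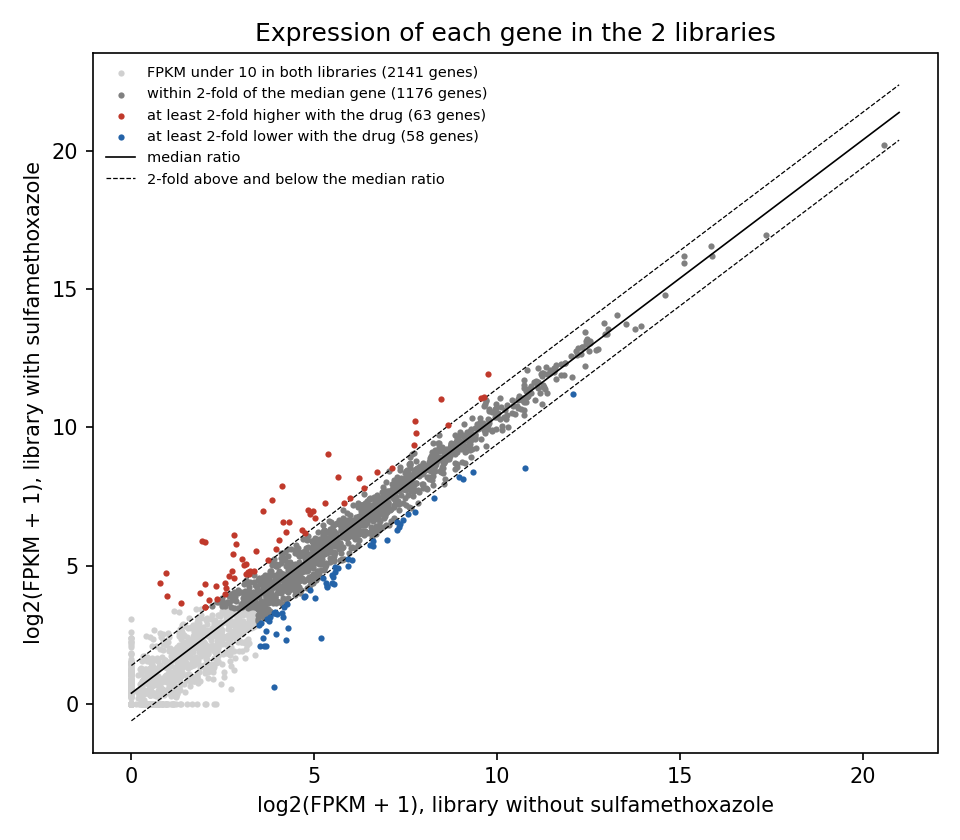
Each point is 1 gene, with log2(FPKM + 1) without sulfamethoxazole on the horizontal axis and with it on the vertical axis. The solid line marks the median ratio and the dashed lines 2-fold on either side, with 63 red genes at least 2-fold higher, 58 blue genes at least 2-fold lower and 1176 dark grey genes between.

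Both libraries ranked the genes much alike. Across the 1297 genes, log2(FPKM + 1) had a Pearson r of 0.97 and a Spearman rho of 0.95 between the libraries. These are correlations across genes within a pair of libraries, and genes are not independent replicates.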

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

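Of the counts of genes, trimmed mean scaling (63 and 55 at 2-fold, 16 and 4 at 4-fold, higher and lower) and a minimum of 20 reads, chosen after seeing the data, stayed within 1.5 times of the main counts of 63, 58, 16 and 4. Without centring, 151 genes were at least 2-fold higher and 17 lower, and 26 were at least 4-fold higher. With TPM, also without centring, these counts were 154, 12 and 26. A pseudocount of 10 gave 36 higher and 30 lower at 2-fold, and 9 higher and 2 lower at 4-fold, while a pseudocount of 0.1 gave 8 lower at 4-fold. Without a filter, 107 were higher and 172 lower at 2-fold and 12 lower at 4-fold, with 3438 genes counted in place of 1297. At 50 FPKM or more, 34 were higher and 20 lower at 2-fold and 1 lower at 4-fold, with 783 genes counted. Leaving out the reads of the most abundant pair of genes, also chosen later and run without centring, gave 8 lower at 4-fold. Asking for a counting interval wholly past the fold, chosen later as well, gave 34 higher and 15 lower at 2-fold and 10 higher at 4-fold. Where no construction is named, the cause was not tested. No printed identifier changed direction under any alternative run for it. These were picked as the extremes of the counted genes, and the filters leave a gene's value unchanged, so this says little about other genes. The alternatives for the gene lists were not run, since no list was filled. Depth limits the low genes most: 132 of the 1297 counted genes had under 50 reads over both libraries. Leaving out replicates was not possible with 1 library per condition.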

Other observations

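In this part, the tests of scaling without the most abundant genes and of identifiers 2 apart were chosen after the results were seen, and the use of identifier order was chosen after seeing the data. The identifiers are numbered in steps of 5 without a gap, and neighbouring numbers are taken here to be neighbouring genes, which no source used here states. In that order there was 1 run of 4 or more genes at least 2-fold apart on the higher side and 1 on the lower side, together 14 of the 121 genes. The number of runs was not above that in 1000 shuffles of the order, which gave up to 1 in each direction, and at 3 or more genes the counts of 1 and 1 stood against up to 3 and 2. The run of genes all at least 2-fold higher with sulfamethoxazole held 8 consecutive identifiers, with folds from 2.82 to 4.49 (median 3.20) and 96 to 1563 reads each. The run of genes at least 2-fold lower held 6, with folds from 2.11 to 2.74 (median 2.31) and 67 to 584 reads each. All 8 and all 6 members had a counting interval on their side of 1. They were picked by their fold in the same reads, so the intervals are no separate support. The shuffles gave no run longer than 4 in either direction. Without centring, with TPM or with a pseudocount of 10, there were 0 runs of 4 or more on the lower side, while the count on the higher side stayed at 1. At 3 or more genes at 4-fold there were 0 runs in either direction.

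Genes at 0 in both libraries also lay together in identifier order. The correlation between neighbouring identifiers of being at 0 in both was 0.40, against at most 0.063 in 1000 shuffles, and 22 runs of 10 or more such identifiers were found, the longest with 55. With a random 50% of the reads of both libraries, a mean of 2055 genes would have been seen over 100 draws, against 2148 with all reads.

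The centred differences of neighbouring identifiers went together, with a Pearson r of 0.42 across 748 pairs of counted genes, against at most 0.12 in 1000 shuffles. Counting noise alone is argued against by the same relation among genes with 50 or more reads, 0.37 against at most 0.13. Reads counted for a pair of overlapping neighbours are argued against as the whole cause by a correlation of 0.24 between identifiers 2 apart (at most 0.12 in shuffles), although at 3 apart, the distance first chosen for this test, the value of 0.11 lay within the shuffles (at most 0.14) over all counted genes and, among genes with 50 or more reads, the value of 0.16 lay above them (at most 0.14). A broad trend along the chromosome is argued against by a correlation of -0.079 between identifiers 50 apart. A hypothesis left open, and not tested, is that co-transcribed genes may account for this relation; genes are not independent replicates, and strand and contig were not used here.

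The FPKM as deposited held many more higher than lower genes, 151 against 17 at 2-fold. Different read totals do not by themselves shift FPKM, which are already divided by the total. Thinning the deeper library to the smaller total left the median log2 difference at 0.38. The division by the total fixes that outcome, so it was no separate test. The most abundant pair of genes held 47.8% of the reads with the drug and 62.5% without it. Because FPKM are divided by the total, this smaller share by itself raises the FPKM of the other genes as a group with the drug. Without the pair's reads the median log2 difference was -0.085, with 59 higher and 80 lower genes. This moves every gene by nearly the same factor, which the read shares already fix, so it was no separate test. Why the share of the pair differed was not tested. No biological explanation was tested.

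After centring, 121 genes were at least 2-fold apart. Counting noise alone is argued against, since 200 simulations with equal levels gave a mean of 13.7 such genes and at most 27. At 4-fold, the 16 higher genes stood against at most 6 in the simulations and the 4 lower genes against at most 3. A difference between single cultures or library preparations rather than the drug cannot be told apart from the drug, because there was 1 library in each condition.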
